A study of Homo sapiens with 8 samples.

How the data were processed

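DNA of HUES64 human embryonic stem cells labelled as a DNMT1 knockout was measured by RRBS at 8 days of DNMT1* withdrawal, day 0 to day 7, with 1 library per day. Per the labels' protocols, libraries were made by a published RRBS method adapted to small cell numbers. The submitters' processing notes name the genome build hg19, and CpG positions on chromosome 1 reach 249239532. The aligner, the methylation caller, read filters and the treatment of duplicate reads are not given in the sources used here.

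The deposited files list 1 CpG per line, 2 bp wide, with its methylated and total reads and its strand. The score that the authors deposited beside them equals 1000 times the methylated share, rounded, in 100% of lines, so the read numbers were used and the score was not. No position was listed more than once. Of 3209182 CpGs listed in any library, 2484802 were in all 8, and 151924 were given on different strands in different libraries. These were joined by position. Starts were changed to count from 1.

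Depth differed widely between libraries. Days 0, 1, 2, 6 and 7 held 161534152, 77691782, 156800949, 141072281 and 140040771 CpG read calls, and days 3, 4 and 5 held 15156251, 12928083 and 12359218. At least 10 reads were found at 94.0% of the listed CpGs on day 0 and at 6.71% on day 5. The labels give no batch, and the 3 shallow days are treated as a possible one. RRBS reads without molecular identifiers are not independent molecules, so Wilson 95% intervals, and the limit of 3 reads behind a share of 0, cover counting error only.

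Common CpGs are autosomal CpGs with 10 or more reads in every library. A library mean weights each CpG equally. CpGs and tiles were put into classes at 80% and 20% by the pooled reads of days 0 and 1. Trends over days were least-squares slopes with standard errors, of means or of their natural logs, and p values came from exact two-sided permutation of the 8 days. Benjamini-Hochberg adjustment covered the 11 such trends. Shares at high, intermediate and low methylation used 10 reads drawn without replacement per CpG and library. Tiles of 1 kb needed 3 or more common CpGs. For each, methylated against unmethylated reads were regressed on day in a quasi-binomial model, the dispersion was moderated with limma's squeezeVar along a trend in the information per tile and kept at 1 or more, and an F test was adjusted by Benjamini-Hochberg at 0.05. A first version without that trend and lower limit made too many false calls on simulated data and was replaced. CpG density was taken as the number of common CpGs in the tile, which also depends on coverage. Retained tiles were those at 80% or more on days 0 and 1 whose pooled reads of days 6 and 7 stood at 1.5 times the median of such tiles or more. With 1 library per day, the means of days 0 and 7 were compared without a test. Fisher's exact test of tiles between these days, an alternative, sets 1 library against 1, and its p values cover counting error only.

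The tile test was tested on simulated reads at the real depths of 2935 tiles, 200 of them changed. It recovered 72%, 62%, 58% and 54% of those changed by -0.4, -0.2, -0.1 and 0.2 log odds per day, with 3 false calls, or 2.38% of all calls. The other steps were tested on simulated reads at every listed CpG. A loss of -0.25 per day on the log scale came back as -0.252 from 22645 highly methylated CpGs. Losses of -0.3 in dense and -0.25 in sparse tiles came back as -0.305 and -0.255 from 26946 and 170269 CpGs in the 5 deep libraries. Of 43 tiles made to keep more, among 533 highly methylated ones, 41 were found, with 0 found in error. These counts hold for the simulated tiles only. The size of the planted excess is not given here, so they cannot say how well tiles near 1.5 times the median are found. Nor do they give the error rate among real tiles, since the 1033 real tiles at 80% or more had a median dispersion of 4.28. Only 9 of these 1033 reached 2 times the median.

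The comparisons, tests and most alternatives were fixed before the data were examined: read minimums of 5 and 20, read weighting, all chromosomes, an upper limit on coverage, class limits of 90% and 10%, tiles of 500 bp and 5 kb, other CpG minimums, tests without moderation, limma on arcsine square-root levels, Fisher's exact test between days 0 and 7, and each day left out. Added after seeing the data were the 5 deep libraries alone, 1 read in place of 10, 10 reads per tile, each day left out for the shares, and CpG density over all listed CpGs. The limits of the density classes were not part of the plan. The named tiles follow the plan's rule for data without an annotation of the same build: the 5 largest fitted falls and 5 largest fitted rises past the threshold, and the 5 highest retained. Planned comparisons of promoters, of gene lists and of exons, introns and repeats need an hg19 annotation, which was not used here, and were not run. The Y chromosome was left out except in the alternative with all chromosomes.

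Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.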

Results

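HUES64 is an established human embryonic stem cell line. In the derivative measured here the labels give the genotype as a DNMT1 knockout, and the time course followed the withdrawal of DNMT1*. DNMT1 is the methyltransferase that copies CpG methylation onto the new strand after DNA replication, and DNMT1* is an exogenous, repressible copy that maintains a line lacking the endogenous enzyme. Reduced representation bisulfite sequencing (RRBS), which reads CpGs near MspI cut sites and so favours CpG-rich DNA, was applied to 1 library per day from day 0 to day 7. There are 8 libraries and no replicates. The trend over days rests on all 8, but on a single course that was not repeated, and single days have 1 library each. The p values of trends therefore do not cover variation between courses.

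The libraries listed between 2816114 and 3185724 CpGs each. Depth fell into 2 ranges. The libraries of days 0, 1, 2, 6 and 7 held 77691782 to 161534152 CpG read calls, with a median of 21 to 44 reads per CpG, and those of days 3, 4 and 5 held 12359218 to 15156251, with a median of 4 reads. In all, 48131 autosomal CpGs had at least 10 reads in every library and are called common CpGs here. A second set of 2496769 autosomal CpGs had at least 10 reads in each of the 5 deep libraries. Days 3 to 5 are 3 libraries, too few for a trend of their own, so values from the 5 deep libraries are given beside those from all 8.

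How far and how fast methylation was lost after withdrawal was read first from the mean over common CpGs. Mean methylation fell on every day, from 56.8% on day 0 to 53.7%, 47.2%, 33.8%, 23.4%, 19% and 12.5% on days 1 to 6 and 10.5% on day 7. The counting error of these means was at most 0.045 points. From day 0 to day 7 the mean fell by 46.3 points, and day 7 kept 18.5% of the day 0 level. Over reads rather than CpGs, 57.3% of reads were methylated on day 0 (Wilson 95% interval 57.2 to 57.3%) and 10.4% on day 7 (10.4 to 10.5%). The 2405476 autosomal CpGs with any read in every library gave a like course, from 55.4% of reads methylated on day 0 to 11.3% on day 7.

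The slope was -7.44 ± 0.56 points per day (SE, n = 8 libraries), with Pearson r = -0.983 and Spearman rho = -1. An exact two-sided permutation test over all 40320 orders of the days gave p = 5e-05 for both, the smallest value it can give, and 0.00011 after Benjamini-Hochberg adjustment over the 11 trends of library values computed. Without days 0 and 7, r was -0.987. Within the 5 deep libraries, over their larger set of 2496769 CpGs, the slope was -6.71 ± 0.45 points per day, with an exact permutation p of 0.0083. The difference between days 0 and 7 has no replicate check.

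**Figure D1:**
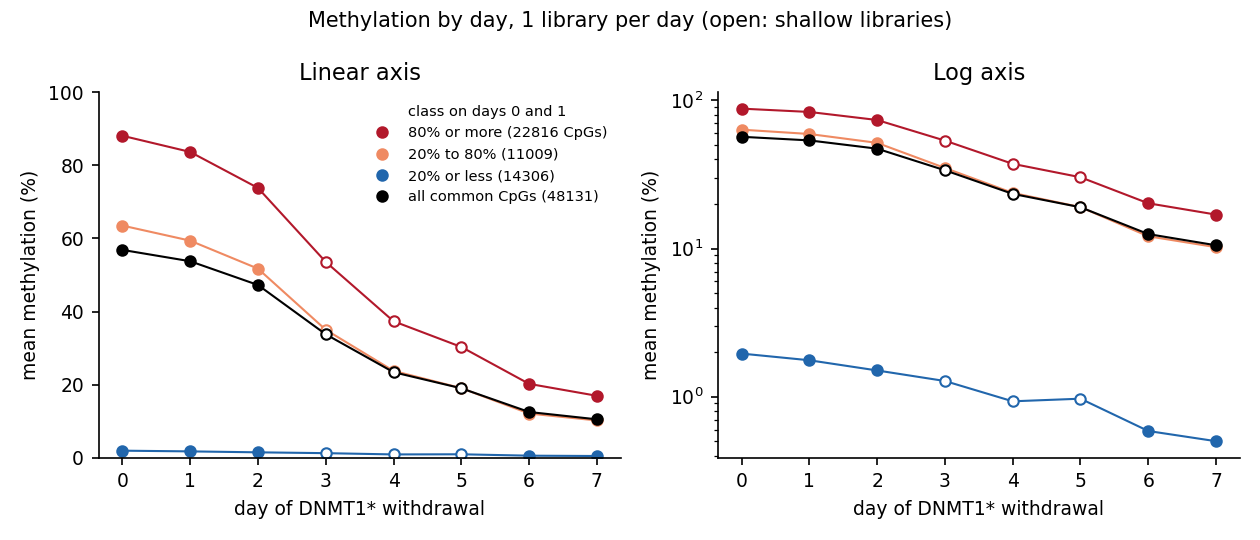
Mean methylation in percent against day of withdrawal, on a linear axis (left) and a log axis (right), for common CpGs together and split by their level on days 0 and 1; each point is 1 library, and open points are the shallow libraries of days 3 to 5. CpGs at 80% or more on days 0 and 1 went from 88.0% to 17.0%, and those at 20% or less from 1.96% to 0.501%.

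The kinetics were then followed in 3 classes set by the pooled reads of days 0 and 1. The 22816 CpGs at 80% or more went from 88.0% on day 0 to 83.6% on day 1, 73.8% on day 2, 53.6% on day 3, 37.3% on day 4, 30.3% on day 5, 20.2% on day 6 and 17.0% on day 7. The first step was the smallest: day 1 kept 95% of the day 0 level and day 2 kept 88.2% of day 1. Each later day kept 66.7 to 83.9% of the day before, with days 5 and 7 losing less than days 3, 4 and 6. The 11009 CpGs between 20% and 80% went from 63.5% to 10.2%, and the 14306 CpGs at 20% or less from 1.96% to 0.501%.

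As an exponential decline, the highly methylated class lost 22.7% of its level per day, a log slope of -0.258 ± 0.018 per day (SE, n = 8; exact permutation p = 5e-05, the smallest possible) and a halving time of 2.69 days. From day 2 on, after the slow start, the halving time was 2.31 days. Within the 5 deep libraries, over the larger set of 1038645 CpGs at 80% or more there, the log slope was -0.244 ± 0.022 per day (exact permutation p = 0.0083). CpGs between 20% and 80% declined faster, at -0.287 per day. Their difference from the highly methylated class was -0.0293 ± 0.0027 per day, with an exact permutation p of 9.9e-05 (adjusted 0.00016). For the same common CpGs in the 5 deep libraries it was -0.0292 (exact permutation p = 0.017). CpGs at 20% or less declined at -0.198 per day, which differed from the highly methylated class by 0.0595 ± 0.0140 per day (exact permutation p = 0.0082, adjusted 0.011). That last difference, for the same common CpGs in the 5 deep libraries, was of like size, 0.0529 ± 0.0132 per day, but did not pass (exact permutation p = 0.092). CpGs below 2% on days 0 and 1 read 0.138 to 0.267% methylated in every library, and this background was not subtracted. On day 7 it was 0.138%, against 0.501% in the class at 20% or less. If it is not real methylation, it flattens the measured decline of that class. The slower rate may thus be partly or mostly background, and the difference without it was not computed.

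How CpG levels were spread on each day was read from the share of common CpGs in each range. For this, 10 reads were drawn per CpG so that depth did not set the ranges. A level is a mean over the cells of a library. The shares therefore cannot tell partial loss in every cell from complete loss in a growing share of cells. CpGs at 80% or more made up 49.9% on day 0, 26.9% on day 2, 6.64% on day 3 and 0.033% on day 7. CpGs at 20% or less rose from 30.7% on day 0 to 55.2% on day 4 and 86.7% on day 7. Those in between rose from 19.4% on day 0 to 53.1% on day 3 and then fell to 13.3% on day 7. On day 7, 45.2% of common CpGs had no methylated read among the 10 drawn, against 25.9% on day 0. Without the draw of 10 reads, the high share was 8.01% on day 2 and 3.12% on day 3, and the intermediate share was largest on day 2, at 61.4%, with 60.6% on day 3.

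The share at high methylation changed by -7.70 ± 1.47 points per day and the share at low methylation by 8.99 ± 1.01 points per day (SE, n = 8; exact permutation p = 5e-05 for each, the smallest possible). The intermediate share, which rose and fell, had no linear trend (exact permutation p = 0.58, adjusted 0.64). For the same common CpGs in the 5 deep libraries, the slopes were -7.36, 9.08 and -1.71 points per day for the high, low and intermediate shares. Their exact permutation p values were 0.0083, 0.0083 and 0.43.

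**Figure D2:**
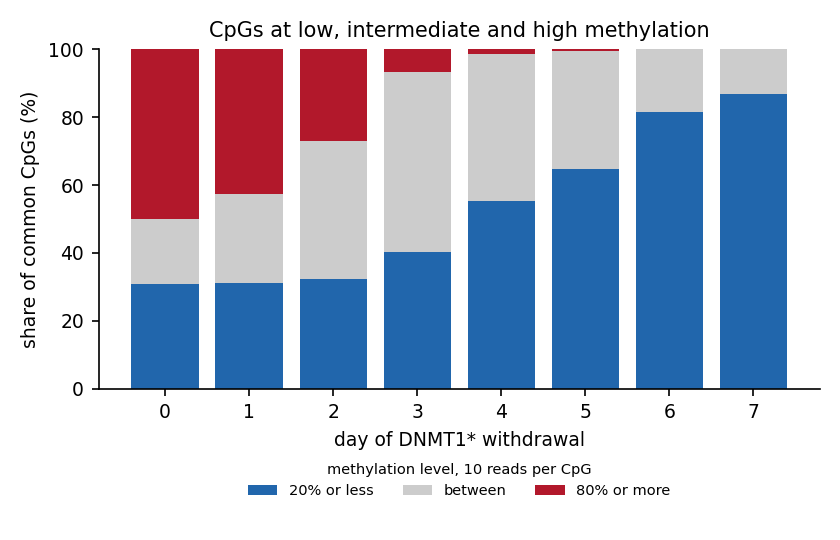
Share of the 48131 common CpGs in percent (stacked bars, 1 library per day) at 20% or less, between, and at 80% or more methylation, with 10 reads drawn per CpG. With this draw the intermediate share is largest on day 3, at 53.1% (without it, on day 2), and the low share reaches 86.7% on day 7.

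Which regions took part was asked in 1-kb tiles of the hg19 genome with at least 3 common CpGs. Of 2935 tiles, 2074 fell over the 8 days and 13 rose at an adjusted p below 0.05 (quasi-binomial regression with dispersions moderated by limma). All 1033 tiles at 80% or more on days 0 and 1 fell, with a median fitted change of -74.5 points, and so did all 836 tiles between 20% and 80%, with a median of -60.5 points. Among 1066 tiles at 20% or less, 205 fell, 13 rose and 848 did not pass. A fall of over 50 points was fitted in 1615 tiles.

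With 10 reads asked of each tile instead of each CpG, a rule added after seeing the data, 214167 tiles could be tested. All 87099 highly methylated tiles fell, and 96015 of 96021 tiles between 20% and 80% did. Of 31047 tiles at 20% or less, 11382 (36.7%) fell, a larger share than the 19.2% of the main set, 309 rose and 19356 did not pass. In the 5 deep libraries alone, 242629 of 263521 tiles fell and 386 rose. The number of rising tiles was not stable: leaving out any 1 day gave between 1 (without day 7) and 6 (without day 4 or day 5), with 5 without each of days 0 to 3 and 4 without day 6, and 3 without moderation of the dispersion.

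The 5 tiles with the largest fitted falls lay at chromosome 8: 1138001 to 1139000, chromosome 6: 168972001 to 168973000, chromosome 12: 122442001 to 122443000, chromosome 8: 38965001 to 38966000 and chromosome 16: 11343001 to 11344000. No gene annotation of hg19 was used, so the genes at these places are not named. The first went from 340 methylated of 366 reads on day 0 (92.9%, Wilson 95% interval 89.8 to 95.1%) to 30 of 309 on day 7 (9.71%, 6.89 to 13.5%), with an adjusted p of 3.0e-07 from the moderated quasi-binomial test. The other 4 had fitted changes of -83.7 to -83.1 points, from 86.0 to 93.8% on day 0 to 6.93 to 15.9% on day 7. The chromosome 8: 38965001 tile read 0 of 33 on day 5, which allows up to 9.09%, and 15.9% on day 7.

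The 5 largest rises were all of about 1 point. They lay at chromosome 16: 30087001 to 30088000, chromosome 3: 134125001 to 134126000, chromosome 5: 68711001 to 68712000, chromosome 5: 72743001 to 72744000 and chromosome 1: 231556001 to 231557000. The chromosome 3 tile had 0 methylated of 768 reads on day 0, which allows up to 0.391%, and 8 of 641 on day 7 (1.25%, Wilson 95% interval 0.634 to 2.44%). The chromosome 16 tile rested on 2 methylated of 182 reads on day 7, the second chromosome 5 tile on 2 of 239 and the chromosome 1 tile on 2 of 279, with 0.355% on day 6. Among the 321 tiles at 20% or less with a rising slope, 14 had an unadjusted p below 0.05 (4.36%; 4.75% with 10 reads per tile and 5.57% in the 5 deep libraries), against 7.71% of rising slopes among unchanged simulated tiles at 20% or less. The simulated tiles were given a spread wider than counting error, whereas the real tiles at 20% or less had a median dispersion of 0.776. The simulated share is therefore not a like measure, and it cannot say whether the rises exceed chance. The 13 rises pass the adjusted threshold beside the many falls.

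Whether loss depended on CpG density was asked with the number of common CpGs per tile: at most 2 (31967 CpGs), 3 to 9 (10283 CpGs) and at least 10 (5881 CpGs). A common CpG needs 10 or more reads in every library, so this number depends on coverage as well as on CpG density. A tile called sparse here may hold many CpGs with few reads. Dense tiles started at 65.7%, sparse tiles at 58.3% and the medium class at 47.2%. This order belongs to the common CpGs: with at least 5 reads per CpG (447842 CpGs) dense tiles started lowest, at 20.5%, the medium class at 53% and sparse tiles at 75.5%, and with at least 20 reads the 3 classes started at 67.4, 68.5 and 71.2%. On day 2 dense tiles kept 86.6% of their day 0 level and sparse tiles 82.0%. On day 7 the order was the other way round, with 16.2% kept in dense and 18.9% in sparse tiles. The medium class kept 84.5% on day 2 and 18.9% on day 7.

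As a single rate over all days, dense tiles declined by -0.284 ± 0.024 and sparse tiles by -0.261 ± 0.017 per day on the log scale. The difference, -0.0229 ± 0.0105 per day, did not pass (exact permutation p = 0.077, adjusted 0.094), nor did it for the same common CpGs within the 5 deep libraries (-0.0257 per day, exact permutation p = 0.075). It passed with at least 20 reads per CpG (-0.0224, exact permutation p = 0.0043), without day 0 (-0.0331, p = 0.040) and without day 4 (-0.0242, p = 0.046). It was smaller and did not pass without day 7 (-0.0137, exact permutation p = 0.32), without day 6 (-0.0189, p = 0.17) and with at least 5 reads per CpG (-0.0165, p = 0.084). The difference between the medium and sparse classes was 0.0012 per day (exact permutation p = 0.81), and passed with at least 5 reads per CpG, at 0.0044 ± 0.0014 per day (exact permutation p = 0.027, not adjusted).

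With density counted over all listed CpGs, a choice made after seeing the data, the same crossing appeared among the 1038645 autosomal CpGs at 80% or more in the 5 deep libraries. Tiles with 40 to 79 listed CpGs kept 86.7% of the day 0 level on day 2 and 19.3% on day 7, and tiles with 1 to 4 kept 82.0% and 21.0%. The difference in the single rate between tiles with 40 or more and 4 or fewer listed CpGs was -0.0146 per day (exact permutation p = 0.13), and -0.0162 (p = 0.14) over all 8 days with at least 5 reads per CpG; neither passed.

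**Figure D3:**
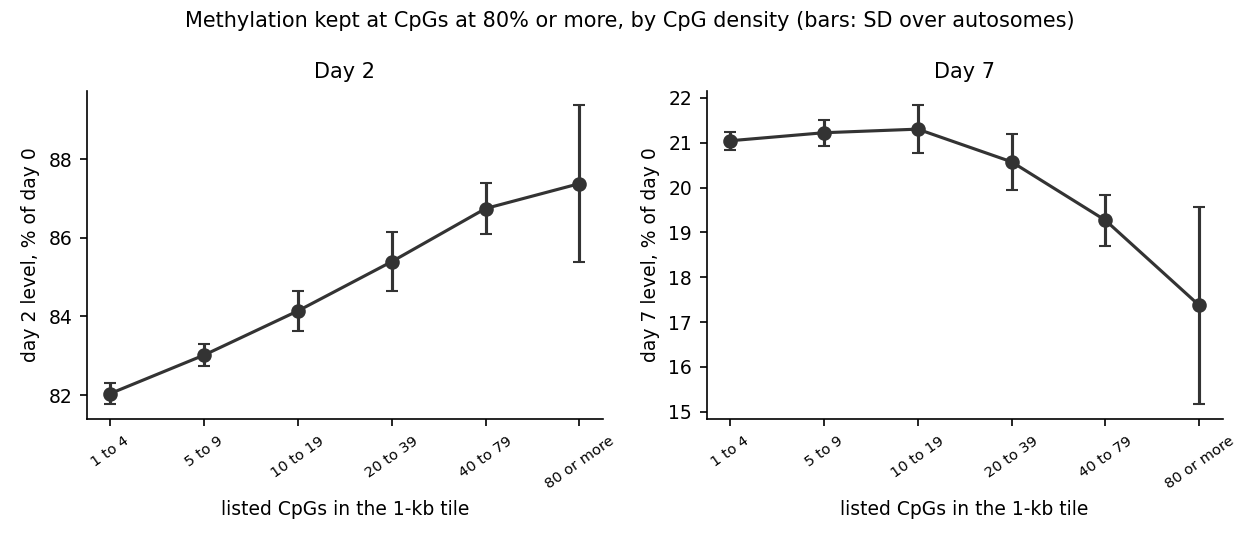
Methylation kept on day 2 (left) and day 7 (right), in percent of the day 0 level, against the number of listed CpGs in the 1-kb tile, for autosomal CpGs at 80% or more on days 0 and 1 in the 5 deep libraries; points are means over CpGs, bars are the SD over autosomes with 20 or more such CpGs, and the vertical axes do not start at 0. The share kept climbs with density on day 2, from 82.0 to 87.4%, and is lowest in the densest tiles on day 7, at 17.4%.

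The last comparison concerned regions that kept methylation. Tiles at 80% or more on days 0 and 1 had a median of 17.9% over the pooled reads of days 6 and 7, and 81 of the 1033 stood at 1.5 times that median or more, that is at 26.8% or above. They lay on 20 of the 22 autosomes and had a median of 29.5% on days 6 and 7, against 17.5% in the other 952. The retained tiles were higher from the start, with medians of 91.4% against 87.5% on day 0 and 79.7% against 74.6% on day 2. On day 5, a library not used to choose them, the medians were 39.6% and 29.8%, and 64 of the 81 lay above the median of the others, as 72 of them had on day 2, so this is not independent of the higher start. At the limit of 1.5 times the median, 31 of the 81 passed on day 5, as did 70 of the other 952 tiles, and the shares kept on day 5 and on days 6 and 7 correlated at r = 0.425 across the 1033 tiles.

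The 5 highest were chromosome 4: 153737001 to 153738000, with 50.4% on days 6 and 7 (Wilson 95% interval 48.5 to 52.3%, 2560 reads), chromosome 9: 3424001 to 3425000 with 48.8% (46.8 to 50.9%, 2247 reads), chromosome 15: 90141001 to 90142000 with 45.9% (43 to 48.8%, 1149 reads), chromosome 3: 174416001 to 174417000 with 44.8% (43.7 to 46.0%, 6935 reads) and chromosome 7: 11034001 to 11035000 with 44.4% (40.2 to 48.8%, 504 reads). All 5 still fell, with fitted changes of -56.3 to -48.9 points over the course. Their day 5 levels were 73.2%, 69.4%, 50%, 57.7% and 70%, in the same order. Only 9 of the 1033 tiles reached 2 times the median. Reads at the chromosome 4, 9 and 3 tiles were 884 to 2220 per CpG on day 0, against a median of 186 in the tiles not retained, and the intervals cover counting error only.

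**Figure D4:**
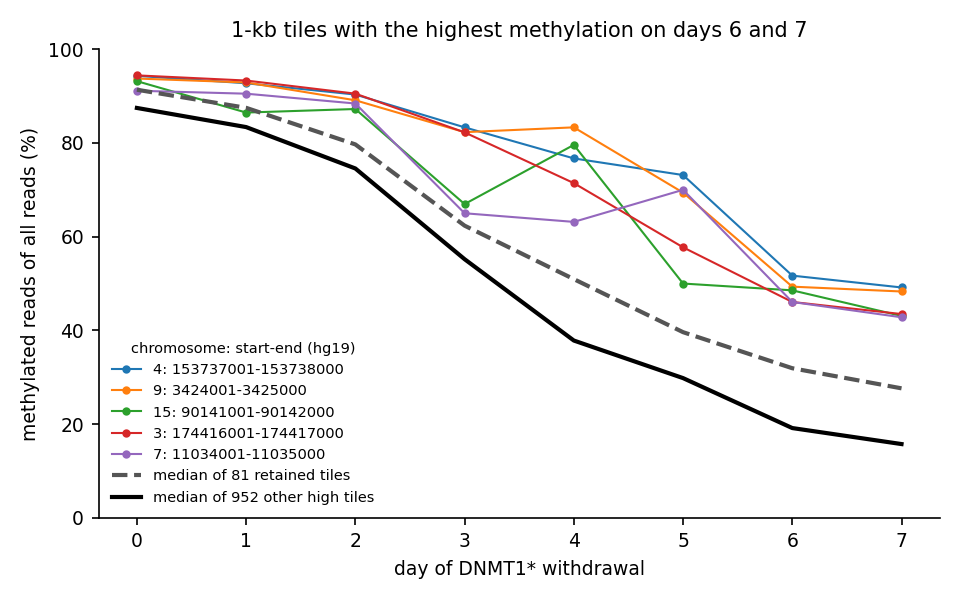
Methylated reads in percent of all reads by day for the 5 tiles with the highest level on days 6 and 7 (thin lines, hg19 coordinates), with the median of the 81 retained tiles (dashed) and of the 952 other tiles at 80% or more on days 0 and 1 (thick). The 5 tiles end between 42.8 and 49.2% on day 7.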

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

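The test of the uneven daily steps, the order of days and the lookup of retained tiles on day 7 were chosen after the results they bear on were seen, as was the comparison of CpG spacings. The tests of CpG density by coverage, starting level and spacing were written down before their values were seen.

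A signal outside the comparisons came from the X chromosome. Its 34843 CpGs at 80% or more on days 0 and 1, with 10 or more reads in the 5 deep libraries, stood at 18.4% on day 7. They kept 20.7% of their day 0 level, inside the range of the 22 autosomes, 20.1 to 21.4%.

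The count of tiles with a trend was set against 99 random orders of the days. The real order gave 2087 tiles, and 1 of 100 orders, the real one, gave as many. All tiles share the same 8 libraries, so the orders ask 1 question of the libraries, not 1 per tile. They cannot tell withdrawal from any other drift between libraries that follows the days. The highest other order gave 2068 tiles, and its ranks correlated with the real order at 0.857. Of the 99 other orders, 87 gave 0 tiles and 12 gave 1339 to 2068, at rank correlations of 0.524 to 0.857 in size with the real order, so an order need not be close to the real one to give a count near it.

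CpG-dense tiles kept more methylation early and less late. In the 5 deep libraries, highly methylated CpGs in tiles with 40 or more listed CpGs kept 86.8% of their day 0 level on day 2, against 82.0% with 4 or fewer, and 19.2% against 21.0% on day 7, with the same signs on all 22 autosomes. A difference in coverage would remove the gap among CpGs with 30 to 60 reads on day 0, where it was -1.68 points on day 7 and 4.52 on day 2. A difference in starting level would remove it among CpGs at 85 to 90%, where it was -2.01 and 5.22 points. Outside recurrent spacings of 6 CpGs the gap was -2.46 and 4.62 points (-2.67 and 4.67 with shorter spacings removed too, a check added later). That step left 36893 of 53583 dense CpGs but 294193 of 295520 sparse ones, since tiles with 4 or fewer listed CpGs can hardly hold such a run. The recurrent spacings in dense tiles thus did not make up the gap. Whether such spacings mark repeats was not tested, so repeat copies without them, in dense or sparse tiles, stay open. A later start and then a faster loss in dense regions may be biological, a hypothesis found and tested on the same libraries, and the difference in the single rate over all days did not pass its test.

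For the 81 retained tiles, counting error alone would not carry over between libraries, but of 76 tiles past 1.5 times the median on day 6, 59 were also past it on day 7, against 32 of the other 957. A candidate explanation is reads shared by copies of interspersed repeats: the same spacing of 4 CpGs (0, 11, 25 and 32 bp) stood in the highest tiles on chromosomes 4 and 9, and 0, 4 and 12 bp in those on chromosomes 15 and 3 and in 2 more on chromosomes 7 and 10, so that 6 of the 7 highest share 1 of 2 spacings, 5 of them with 884 to 2220 reads per CpG on day 0. Over the set, 27 of 70 retained tiles searched held a spacing of 4 CpGs that recurred across the autosomes, against 205 of 811 others, an odds ratio of 1.86 with a Fisher exact p of 0.023, but 1.44 with p = 0.18 without the 7 highest tiles. With spacings of 6 CpGs it did not pass: 21 of 81 retained tiles held one against 164 of 952 others, an odds ratio of 1.68 with a Fisher exact p of 0.068, where tiles with no run to search counted as holding none. Repeat copies are thus a candidate source for the highest tiles and stay open for the rest. Median reads per CpG on day 0 were 158 over all retained and 186 over all other tiles. Both sets consist of common CpGs, which had a median of 152 reads on day 0, against 44 over all listed CpGs. These medians therefore cannot tell whether reads piled up. The design holds no group that would test a biological explanation.

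The daily steps were uneven around days 3 to 5. In the highly methylated class, day 5 lay 2.36 points above the exponential line between days 2 and 6, and days 3 and 4 departed from it by 0.175 and -1.29 points. The sizes, and the sign on day 3, depend on the CpGs taken: with 1 or more read in every library and each read equal, the departures of days 3, 4 and 5 were -1.60, -2.71 and 1.44 points in that class, and -1.83, -1.92 and 0.413 points over CpGs of all levels. A higher background in the shallow libraries was too small to account for that, since the level of CpGs below 2% differed by at most 0.128 points between libraries. A library batch of those 3 days could give the same departure, and it cannot be told apart from a real change of pace because these days have no deep library; no biological explanation was tested.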

How the results depend on the processing

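The fall in the mean, the rate of loss and the trends of the high and low shares kept their direction and passed their tests under every alternative run. Slopes of the mean ranged from -9.24 to -6.71 points per day and log rates from -0.300 to -0.244 per day; a straight line in place of the log fit gave -11.4 points per day. The intermediate share had no trend under any of its alternatives (p from 0.20 to 0.85). Day 7 minus day 0 was -43.7 points with 5 reads, -57.1 with 20 reads, -46.8 with each read equal, -46.6 on all chromosomes, -45.1 without the top 0.1% of coverage, -44.1 with 1 read and -42.9 in the deep libraries, and -44.3 to -43.2 with day 6 or day 1 as the end. CpG sets differ in starting level; how far that makes up these shifts was not tested. The dense-sparse difference ranged from -0.0331 (without day 0) to -0.0137 (without day 7); it passed without day 0, without day 4 (-0.0242) and with 20 reads (-0.0224), and the cause was not tested.

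Tiles with a trend, 71.1% of those tested, numbered 41138 of 55575 (74.0%; 137 rising) with 5 reads, 420 of 428 (98.1%; 0 rising) with 20 reads, 22761 of 30229 (75.3%; 70 rising) with 1 CpG or more, 639 of 804 (79.5%; 3 rising) with 5 CpGs or more, 194805 of 214167 (91.0%; 309 rising) with 10 reads per tile, and 243015 of 263521 (92.2%; 386 rising) in the deep libraries. Rising tiles numbered 3 without moderation, 6 with limma on arcsine levels, 4 by Fisher's exact test, which compares 1 library of day 0 with 1 of day 7 and covers counting error only, and 1 to 6 with a day left out; the cause was not tested. Retained tiles, 7.84% of 1033, numbered 9 (0.871%) at 2 times the median, 18 of 284 (6.34%) with 5 CpGs or more, 18 of 147 (12.2%) with 20 reads and 4596 of 87099 (5.28%) with 10 reads per tile. The deep-library, 1-read and per-tile alternatives were chosen after seeing the data. No paired analysis was possible because each day has 1 library. Promoter and gene-list alternatives were not run. The 4 reads per CpG at the median on days 3 to 5 set the size of the common set.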

Other observations

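The comparisons in this part were chosen after seeing the data and are given as values. Whole-chromosome averages of the loss differed little. Among 1038645 autosomal CpGs at 80% or more on days 0 and 1 in the 5 deep libraries, day 7 kept 21.0% of the day 0 level. By chromosome the share kept ran from 20.1% on chromosome 18 to 21.4% on chromosome 19, with an SD of 0.31 points over the 22 autosomes, although the mean over all CpGs on day 0 ran from 50.9 to 59.8%. With CpG density in 6 steps, the share kept on day 2 climbed at each step, from 82.0% in tiles with 1 to 4 listed CpGs to 87.4% in tiles with 80 or more. On day 7 it was 21.0 to 21.3% up to 19 CpGs per tile, 20.6% at 20 to 39, 19.3% at 40 to 79 and 17.4% at 80 or more. Between days 2 and 7 the sparsest tiles kept 25.7% and the densest 19.9%.

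What single CpGs kept on day 6 correlated with what they kept on day 7, and less so between different CpGs. Among 977873 highly methylated CpGs with 20 or more reads on days 6 and 7, the level left on day 6 correlated with that on day 7 at r = 0.521, after removing a linear effect of the starting level. The day 6 level of one CpG against the day 7 level of another gave r = 0.209 at 2 to 50 bp, 0.118 at 50 to 200 bp, 0.122 at 200 to 1000 bp, 0.0783 at 1000 to 5000 bp and 0.0141 at 20000 to 100000 bp. These correlations are across CpGs, which are not independent replicates. Days 6 and 7 are successive days of 1 course, so the values do not show whether a second course would keep the same CpGs.

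Recurrent spacings of CpGs kept different amounts; whether they mark repeat families was not tested, since no repeat annotation was used. Distinct spacings of 6 CpGs (the same 5 gaps) found at 20 or more autosomal places numbered 1759, in 123556 runs, against 80 spacings after shuffling gaps. Of these, 414 lay on 5 or more chromosomes and stood at 80% or more on days 0 and 1. The share of their methylated reads kept on days 6 and 7 had a median of 24.2%, with 5th and 95th percentiles of 20.9 and 28.2%. The amounts on day 6 and day 7 correlated at r = 0.851 across families, some of which overlap. The highest, with gaps of 13, 7, 9, 8 and 8 bp at 187 places on 22 chromosomes, kept 31.6% (bootstrap 95% interval over places 31.1 to 32.0%). The lowest, with gaps of 30, 3, 22, 2 and 4 bp at 31 places on 5 chromosomes, kept 16.1% (14.9 to 17.4%).

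Of the 96021 tiles between 20% and 80% in the set with 10 reads per tile, 6 did not pass the trend test. The 2 at chromosome 21: 9825001 to 9826000 and 9826001 to 9827000 (hg19) had 3441 and 3499 reads per CpG on day 0, against a median of 52.2, and went from 24.6 to 4.85% and from 23.4 to 4.27% between days 0 and 7. The 309 rising tiles of that set had a median fitted rise of 0.368 points, and 1 rose by over 5 points.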
